A study of Rattus norvegicus with 6 samples.

How the data were processed

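Liver RNA from 6 Sprague-Dawley rat pups aged 3 weeks was measured on Affymetrix rat expression arrays, 1 array per sample. Three-prime labelled RNA is hybridised to short probes on these arrays, and several probes are summarised into 1 value per probe set. Per the labels, 3 samples came from pups of dams on a control diet and 3 from pups of dams on a high fat diet. RNA was extracted with TRIzol, checked on a Bioanalyzer and labelled with a 3' IVT kit, per the labels' protocols.

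The deposited values are on a log2 scale, as found from the values themselves. Only base 2 gives every array the same 2% trimmed mean after the logarithm is undone, 500.2 on each array, which is a scaling of each array as a whole. The lowest deposited log2 values had been set to 0, at 91 to 144 of the 31099 probe sets per array. The summarization software is not given in the sources used here. Quartiles differed between arrays by up to 0.22 log2 units, above the limit of 0.1 set in advance, so the arrays were quantile-normalized.

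The 57 control probe sets were left out of the tests. Of the other 31042, 20826 were paired with 1 gene in the annotation given, 436 with several genes and 9780 were not named here. Symbols were updated through a current rat gene table, which matched 20758 of the 20826. Probe sets with several genes or none entered the normalization and the brightness limit below, and otherwise only the counts over every probe set. A gene with several probe sets took the one with the highest mean over all arrays. The lowest 40% of probe sets by mean, below 5.83 on the log2 scale, were left out, leaving 10372 of 14217 genes. No detection calls were used here, so levels near the floor have no lower bound of their own and folds of dim genes are the measured ones.

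Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment over all genes tested. Every adjusted p is limma's, and fold changes are high fat minus control on the log2 scale with limma's standard error (SE). A looser list took genes at an unadjusted p under 0.05 and at least 1.5-fold. Of 31 gene lists, 29 were tested with camera at a preset correlation of 0.01. The skeletal muscle list had under 5 genes measured, and the list of sex-linked transcripts was only read per array. Camera with an estimated correlation and fry were run beside it. Camera asks whether a list's genes shift more than other genes, and fry whether they move on balance one way. Single values were compared with exact permutation tests over the 10 splits of the arrays, which cannot give a p below 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

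The tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took up to 12 genes per direction, ranked by fold change among those past the adjusted threshold with all arrays of a group on one side. It was filled from the looser list where fewer passed. It added the 3 members of each list with the smallest p, or 5 for a list past its threshold, and 18 anchor genes, 14 of which were measured. Further genes in the text were chosen after their values were seen. Of the named genes, 41 had several probe sets, and for 6 (Eci1, Gpr182, Insr, Nkd1, Slc1a2 and Sox4) these differed in sign.

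The procedure was tested on simulated data for this comparison, with the spread of 10372 genes drawn from the model's own fit. It recovered 58% of 50 genes changed 2-fold, 96% of those changed 4-fold, 98% at 8-fold and 100% at 16-fold. It called 6 unchanged genes. None of the unshifted lists was called, and a list shifted by 0.50 was. The genes were simulated independently of each other. In the real arrays the estimated correlation reached 0.79, for cholesterol synthesis and uptake. The simulation therefore does not show how often correlated lists are called by error. Nor do the recovered shares carry over to the real genes. The adjusted threshold depends on how many genes change, which the simulation set. In the real arrays Sqle, 16-fold lower, and Acot1, 12-fold higher, did not pass (limma adjusted p = 0.131 and 0.184).

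The labels number the samples 1 to 3 within each diet, which served here as replicate numbers, and call every one biological replicate 1. They name no litters, so p-values measure the spread between these pups, and pups of 1 litter would share a dam. The number of arrays limits the precision. Alternatives covered the normalization, the brightness filter, the handling of several probe sets, the variance model, array weights, the replicate number as a block, thresholds and each array left out. Leaving out high fat replicates 1 and 3 together and a covariate for RNA integrity were added after the data were seen. No genome was used, so no positions are given.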

Results

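Liver transcript levels of 3-week-old rat pups were compared between 3 pups of dams fed a high fat diet and 3 pups of dams fed standard chow. Weaning was the age chosen, and the comparison asks how the diet of the mother relates to the liver of the offspring. After filtering, 10372 genes were tested.

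Pups of high fat dams had far more transcript of Scd, the desaturase that makes monounsaturated fatty acids. Its log2 signal was 11.23 ± 0.38 (SD, n = 3) against 6.55 ± 0.41 (SD, n = 3) in controls, 25.6-fold higher (log2 change 4.68, SE 0.27, adjusted p = 0.00696). Psat1, an enzyme of serine synthesis, rose 7.59-fold (2.92, SE 0.25, adjusted p = 0.0254), and Retsat, which saturates retinol, rose 3.17-fold (1.67, SE 0.14, adjusted p = 0.0254). Faxdc2, a gene of the fatty acid hydroxylase family, was 6.30-fold lower (log2 change -2.66, SE 0.20, adjusted p = 0.0181). These 4 genes, 3 higher and 1 lower, were all that passed an adjusted p under 0.05. No gene passed in limma without control replicate 1 or without control replicate 3, where 1313 and 1144 genes had an unadjusted p under 0.05. Scd was the only gene to pass without control replicate 2 or without high fat replicate 2, and Scd and Faxdc2 passed without high fat replicate 1. Without high fat replicate 3, Scd, Psat1 and Tm7sf2, a gene of cholesterol synthesis, passed.

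**Figure D1:**
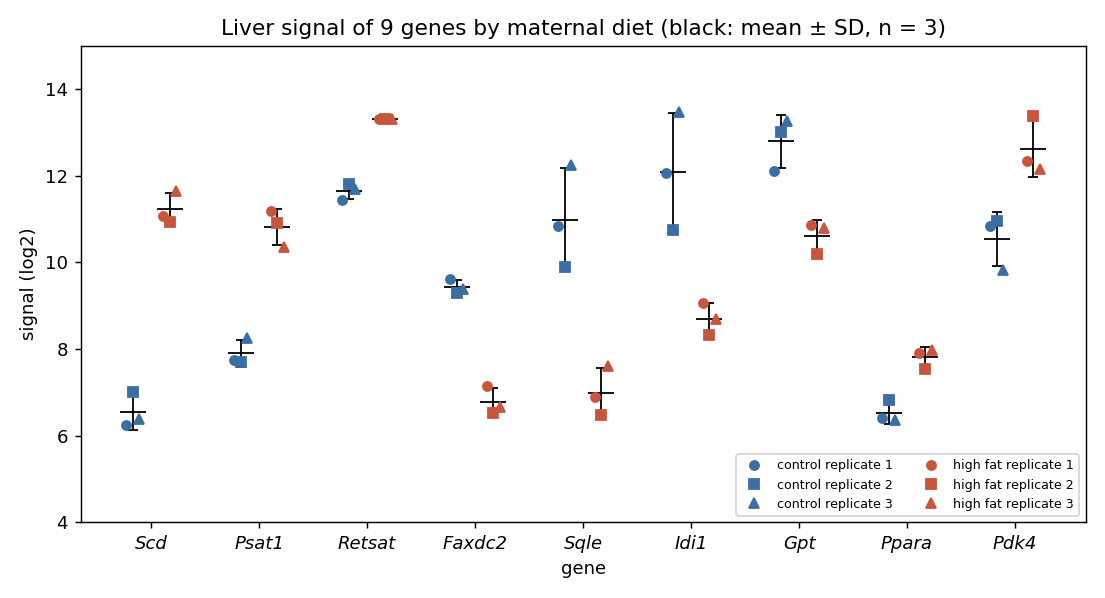
Log2 signal (vertical axis) of 9 genes (horizontal axis) on each of the 6 arrays, blue for control and red for high fat pups, with black bars for the mean ± SD (n = 3). Scd lies at 6.23 to 7.02 in controls and at 10.94 to 11.66 in high fat pups, while Sqle spreads widely among the controls.

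With these 4 included, 694 genes had an unadjusted p under 0.05 and at least 1.5-fold, 346 higher and 348 lower. At an unadjusted p under 0.05 alone there were 1456 genes, where chance gives 519 on average. Other splits of the same 6 arrays gave 312 to 735 genes in limma. In 2161 genes, 20.8%, all high fat arrays lay on one side of all control arrays, where chance gives 10%. Among the other genes of this looser list, which did not pass the adjusted test, the largest differences upward were Hspa1a, a heat shock chaperone (4.02, SE 1.45), and Acot1, an acyl-CoA thioesterase (3.58, SE 0.79). The serine synthesis enzyme Phgdh followed at 3.14 (SE 0.40), then the cationic amino acid transporter Slc7a1 at 2.85 (SE 0.48) and asparagine synthetase, Asns, at 2.74 (SE 0.36). Nrep at 2.53, Serpina6, which encodes the corticosteroid-binding globulin, at 2.32, Gstp3 at 2.28 and Dact2 at 2.26 completed that side. Downward, Sqle (-4.0, SE 0.59) and Idi1 (-3.40, SE 0.63), both of sterol synthesis, stood first. Aldoc (-3.06), Ntf3 (-2.95), the citrate transporter Slc13a5 (-2.85), Msmo1 (-2.81), Cyp2a3 (-2.68), Nfe2 (-2.44), Acat2 (-2.36), Hsd17b7 (-2.34) and Cyp1a1 (-2.33) came next. Hspa1a rested on high fat replicates 2 and 3, at 14.19 and 12.60, since replicate 1 was at 7.91 and controls at 7.18 to 7.90. Ntf3 leaned on high fat replicate 1, at 2.25 against 6.12 and 7.02 in the others, and was at -1.51 without it. Cyp1a1 was at -1.38 without high fat replicate 2. Aldoc had a mean of 5.85, close to the brightness limit of 5.83, and lay below that limit in high fat replicates 2 and 3, at 3.19 and 3.69. Slc7a1 ranged from 1.27 to 3.25 with 1 array left out; its lowest value came without high fat replicate 2, where another probe set, at 1.59 over all arrays, took its place.

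Cholesterol synthesis genes lay lower as a group in pups of high fat dams. All 20 measured genes of cholesterol synthesis and uptake were lower, with a median log2 change of -1.69, and 16 passed when adjusted over the list alone (none over all genes tested). The list had a camera adjusted p of 1.14e-14 (adjusted p = 0.496 with an estimated correlation). Squalene epoxidase, Sqle, was 16-fold lower (adjusted p over the list alone 0.00533), Idi1 10.6-fold, Msmo1 6.99-fold, Hsd17b7 5.05-fold and Dhcr7, the last step of the pathway, 3.30-fold. Srebf2, the transcription factor of this pathway, was at -1.30 (SE 0.36). Controls varied widely among themselves, with list medians from -0.68 to 0.86 around their own mean, while high fat pups lay at -1.60, -1.84 and -1.33. The median change was -1.21 without control replicate 3, the highest control, and -2.06 without control replicate 2, the lowest. With the covariate for RNA integrity it was -1.21. Control replicate 3 also had the highest 3' minus 5' differences of all arrays.

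Fatty acid synthesis genes went both ways. Of 22 measured genes of fatty acid and triglyceride synthesis, 14 were higher and 8 lower, and 2 higher genes, Scd and Me1, passed when adjusted over the list alone. The median was 0.30 and camera's adjusted p 0.0528 (adjusted p = 0.496 with an estimated correlation). Me1, which supplies NADPH, was 1.86-fold higher and Thrsp 2.64-fold. Fasn, the fatty acid synthase, had a log2 change of -1.73 (SE 0.63) and its regulator Srebf1 0.39 (SE 0.38), neither past the test. With 1 array left out, Srebf1 ranged from 0.16 to 0.80, and Fasn was at -1.0 without control replicate 3. The list passed in 6 of 18 alternatives, with an adjusted p of 0.0186 without control replicate 3, 0.0246 and 0.0297 without high fat replicates 2 and 3, and 0.00237 (median 0.48) with the covariate for RNA integrity. Without control replicate 1 it was at 0.338, with a median of 0.16.

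Targets of PPAR alpha, the fatty acid sensor of the liver, lay higher in high fat pups. Of 25 such genes outside fatty acid oxidation, 23 were higher, with a median of 0.65, and 8 passed when adjusted over the list alone (none over all genes tested). The list had a camera adjusted p of 4.95e-10 (adjusted p = 0.496 with an estimated correlation). Ppara itself was 2.45-fold higher (1.29, SE 0.19). Pdk4, which restrains glucose oxidation, was 4.21-fold higher, Acot1 12-fold, Acot2 2.77-fold, Cyp4a1 1.66-fold and the hormone Fgf21 4.54-fold (2.18, SE 0.58). Fatty acid oxidation and ketogenesis genes shifted less, with 19 of 23 higher and a median of 0.20 (camera adjusted p = 0.00385; adjusted p = 0.685 with an estimated correlation). Only Ehhadh, of the peroxisomal pathway, passed within that list, at 2.86-fold. Bdh1 (0.83), Eci1 (0.53), Eci2 (0.30), Acat1 (0.32) and Cpt1a (0.40, SE 0.32) did not. Without control replicate 3 the oxidation list had a median of 0.10 and an adjusted p of 0.0548, with Cpt1a at 0.052, Eci1 at 0.35 and Acat1 at 0.19; Cpt1a was at 0.69 without control replicate 2.

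Genes of the urea cycle and amino acid breakdown lay lower, 27 of 31, with a median of -0.51, and 11 passed when adjusted over the list alone (none over all genes tested). Camera's adjusted p was 6.77e-06 (adjusted p = 0.496 with an estimated correlation), and the median was -0.31 without control replicate 2. Gpt, alanine aminotransferase, was 4.54-fold lower, Hal, which breaks down histidine, 3.31-fold, Cbs 2.00-fold, Nags, which makes the activator of the urea cycle, 1.76-fold and Aass 1.47-fold. Mitochondrial respiratory chain genes showed a small shift shared by most members. In that list 48 of 50 were lower, with a median of -0.19, and none passed when adjusted over the list alone. In camera this gave an adjusted p of 1.86e-06 (adjusted p = 0.496 with an estimated correlation). The complex I subunits Ndufs4 (-0.61, SE 0.15) and Ndufa5 (-0.52, SE 0.12) had the largest differences named, ahead of Ndufa2 (-0.35), Uqcrh (-0.34) and Ndufb9 (-0.32).

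**Figure D2:**
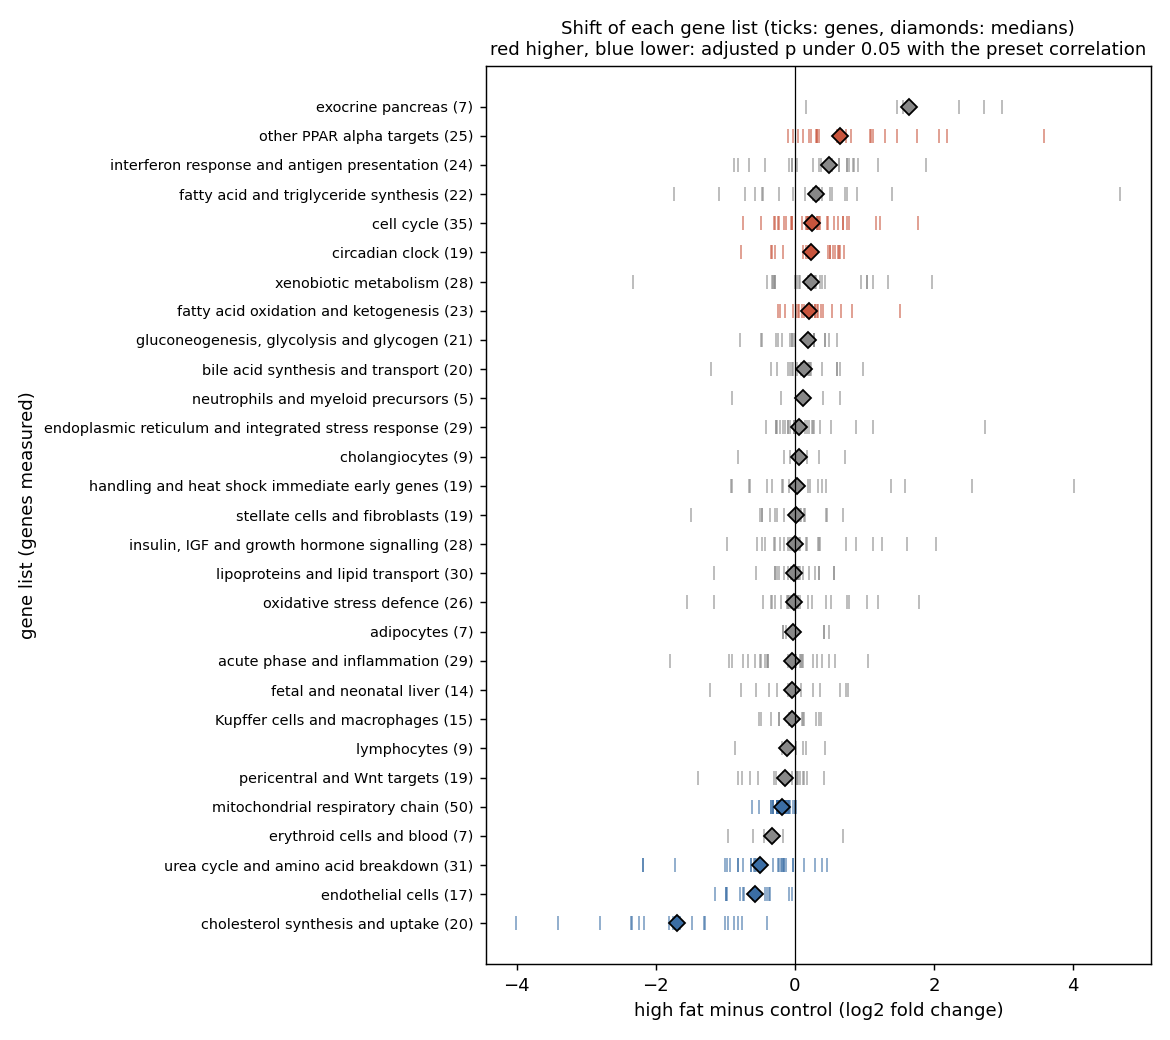
Log2 fold change, high fat minus control (horizontal axis), of every measured gene (ticks) in each of the 29 tested lists (vertical axis), with diamonds for list medians. Red and blue mark the 4 higher and 4 lower lists past an adjusted p under 0.05 with the preset correlation, and cholesterol synthesis and uptake lies lowest, with a median of -1.69.

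Endothelial markers were lower in the high fat pups, all 17 measured, with a median of -0.57. Of these, 8 passed when adjusted over the list alone (none over all genes tested), and camera's adjusted p was 2.18e-07 (adjusted p = 0.496 with an estimated correlation). Several are scavenger receptors of the liver sinusoid, such as Stab2 (-0.97, SE 0.23), Stab1 (-0.61, SE 0.16) and Fcgr2b (-0.99, SE 0.23). Lyve1 was at -0.57 (SE 0.12) and Gpr182 at -0.73 (SE 0.20). The list's median was lowest in high fat replicate 1, at -0.99, against -0.40 and -0.56 in the others. That array also carried exocrine pancreas transcripts. Prss1, a trypsinogen, was at 13.08 there and at 4.10 to 5.30 in the other arrays, and the 7 pancreas genes tested had a median of 6.30 above the control mean in that array, against -0.17 and 0.37.

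Other cell types showed no list past the threshold. Kupffer cells and macrophages had a median of -0.04 (camera adjusted p = 0.708), with Cd163 at -0.52, Cd14 at -0.49 and Mrc1 at -0.34. That median was 0.12 without high fat replicate 2 and -0.18 without high fat replicate 3. Stellate cells and fibroblasts had a median of 0.02, against a mean of -0.10 and a downward test (adjusted p = 0.825), with Dcn at -1.50, Pdgfrb at -0.48 and Lrat at 0.70. Cholangiocytes were at 0.05 (adjusted p = 0.631), though Cdh1, the epithelial cadherin, passed within that list at -0.82, while Krt19 was at 0.72 and Prom1 at 0.35. Lymphocytes were at -0.11 (adjusted p = 0.984; Jchain 0.43, Zap70 -0.86, Gzma -0.13) and neutrophils and myeloid precursors at 0.11 (adjusted p = 0.631; Np4 0.41, Defa5 0.66, Lcn2 -0.90). The neutrophil and myeloid median ranged from -0.26 without high fat replicate 3 to 0.51 without high fat replicate 2, and Lcn2 from -1.70 to -0.060 with 1 array left out. Erythroid genes were at -0.33 (adjusted p = 0.181), with Slc4a1 at -0.96, Tfrc at -0.61 and Epor at 0.70, and the list's median was -0.083 without control replicate 1 (adjusted p = 0.583) and -0.66 without control replicate 3 (adjusted p = 0.0196). Adipocyte genes had a median of -0.03 and a mean of 0.12 with an upward test (adjusted p = 0.690; Pparg 0.49, Car3 0.43, Plin4 0.42). The exocrine pancreas list had a median of 1.64 (adjusted p = 0.102), carried by high fat replicate 1, with Prss1 at 2.98 (SE 2.04), Cela2a at 2.72 and Pnlip at 2.35. It passed in 5 of 15 alternatives, with a median of 2.99 and an adjusted p of 0.00187 without high fat replicate 2. Without high fat replicate 1, under 5 of its genes passed the brightness filter, so the list could not be tested there. Cd163, Prom1, Jchain, Zap70, Gzma, Np4, Defa5, Epor, Pparg, Car3, Plin4, Cela2a and Pnlip moved by over 1.5 times with 1 array left out. Epor did so only without control replicate 2, where another probe set, at 0.38 over all arrays, took its place.

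Cell cycle genes had a median of 0.25, with 24 of 35 higher and 3 past the test when adjusted over the list alone. Camera's adjusted p was 0.0179 (adjusted p = 0.771 with an estimated correlation). Ccnd1 was 2.34-fold higher, Ccne2 3.39-fold, Mcm7 1.68-fold, Pcna 1.48-fold and Cenpf 1.71-fold. The shift rested most on high fat replicate 3, at 0.88 above the control mean against 0.05 and -0.33. Without it the median was -0.10 and the adjusted p 0.817. Without control replicate 3 the median was 0.037 (adjusted p = 0.285), and without control replicate 2 the adjusted p was 0.0501. The median rose to 0.45 without control replicate 1 and to 0.53 without high fat replicate 2. High fat replicate 3 also had the highest medians of the interferon (1.01), neutrophil and myeloid (0.56) and Kupffer cell (0.32) lists. In that array Xist, the RNA of the inactive X chromosome, was low, at 4.45 against 12.46 to 13.31 in the others, and the Y-linked Eif2s3y was high, at 11.14 against at most 3.99. The brighter probe set of Uty, also Y-linked, did not follow, at 10.26 there and 10.64 to 11.20 in the others.

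**Figure D3:**
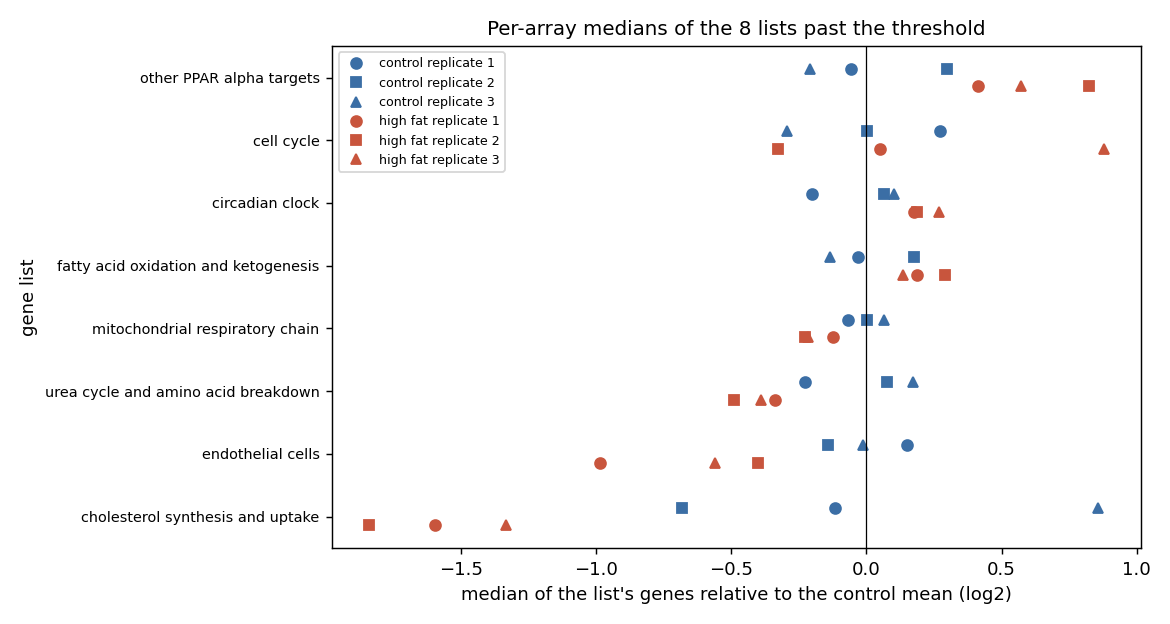
Median log2 level of the genes of each of the 8 lists past the threshold (vertical axis) on each array, relative to the control mean (horizontal axis), blue for control and red for high fat pups. The cell cycle median stands at 0.88 in high fat replicate 3 and at -0.33 in high fat replicate 2.

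Circadian clock genes had a median of 0.23, with 14 of 19 higher and none past the test when adjusted over the list alone. Camera's adjusted p was 0.0179 (adjusted p = 0.496 with an estimated correlation), and 0.285 without control replicate 1; the median was 0.48 without control replicate 2. The repressors Nr1d2 (0.61, SE 0.17), Cry1 (0.64, SE 0.19) and Nr1d1 (0.64, SE 0.29) and the activator Bmal1 (0.70, SE 0.30) had positive values, as did Csnk1e (0.51). The output gene Dbp was at 0.15 (SE 0.58). With 1 array left out, Dbp ranged from -0.36 to 0.69 and Nr1d1 from 0.37 to 0.93.

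The remaining pathway lists did not pass camera's threshold. Of all 21 lists outside it, 10 passed in at least 1 alternative, and 12 had medians on both sides of 0 with 1 array left out. Insulin, IGF and growth hormone signalling had a median of 0.01 (adjusted p = 0.181), yet Igfals (2.39-fold) and Ghr (1.67-fold), of the growth hormone axis, passed when adjusted over the list alone. Irs2 was at 1.61 (SE 0.45), Igfbp1 at 1.13 (SE 0.42), Igf1 at 0.36 (SE 0.14) and Insr at -0.15 (SE 0.16). Oxidative stress defence had a median of -0.01, a mean of 0.09 and an upward test (adjusted p = 0.349), with both subunits of the glutathione-synthesis enzyme higher, Gclm (0.79, past the test within the list) and Gclc (1.19), and Slc7a11 at 1.79. The endoplasmic reticulum and integrated stress response list was at 0.06 (adjusted p = 0.252; 0.000265 without control replicate 1). Asns alone passed within it, with Trib3 at 0.88 and Ddit4 at -0.42. Pericentral and Wnt targets were at -0.15 (adjusted p = 0.107; 0.0125 without high fat replicate 3), and Oat (-1.39), Nkd1 (-0.81) and Slc1a2 (-0.75) passed within that list.

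Fetal and neonatal liver genes had a median and a mean of -0.04 with an upward test (adjusted p = 0.882). Within that list the imprinted Meg3 (-1.22) and Cdkn1c (-0.78) and the transcription factor gene Sox4 (0.65) passed. Lipoproteins and lipid transport were at -0.01 (adjusted p = 0.968), where Angptl8, an insulin-induced regulator of lipoprotein lipase, passed within the list at -1.17, with Lipc at 0.34 and Apom at -0.28. Bile acid synthesis and transport had a median of 0.12 (adjusted p = 0.105; 0.0246 without high fat replicate 2), with Akr1d1 at 0.64 (0.52 to 1.53 with 1 array left out, the highest on another probe set), Cyp8b1 at -1.20 (-0.74 without high fat replicate 1), Slco1a4 at 0.61 and Cyp7a1, the rate-limiting enzyme, at 0.21 (SE 0.26). Gluconeogenesis, glycolysis and glycogen were at 0.18 (adjusted p = 0.460), with Pgam1 at -0.47, Tpi1 at -0.48, Pck2 at 0.49 and Pck1 at 0.27 (SE 0.21). G6pc shared its probe sets with other genes. Xenobiotic metabolism was at 0.23 (adjusted p = 0.129, and 0.0411 without control replicate 2; Ephx1 1.04, Cyp1a1 -2.33, Ugt2b1 -0.40). Acute phase and inflammation were at -0.04 (adjusted p = 0.181), with Orm1 at -0.95, Icam1 at -0.58 and Cd14 at -0.49. Camera's adjusted p for that list was 0.0459 with the values as deposited, 0.00794 with the covariate for RNA integrity and 0.0487 without control replicate 3. The median ranged from -0.15 without high fat replicate 2 to 0.005 without control replicate 1. The interferon response was at 0.49 (adjusted p = 0.205), with 17 of 24 genes higher and 7 lower, Stat2 at -0.66, Ifit1 at -0.82 and Gbp2 at 0.78. Its median was 0.87 without control replicate 2 (adjusted p = 0.00295) and 0.71 without high fat replicate 2 (adjusted p = 0.00185), but 0.037 without control replicate 3 (adjusted p = 0.677) and 0.056 without high fat replicate 3 (adjusted p = 0.903). Handling and heat shock genes were at 0.03 (adjusted p = 0.813), with Hsph1 at 1.59, Klf4 at -0.90 and Ier3 at -0.65. Irs2, Igfbp1, Insr, Trib3, Cyp7a1, Pck1, Ifit1 and Gbp2 of these lists moved by over 1.5 times with 1 array left out.

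In all, camera called 8 of 29 lists with the preset correlation, 4 higher and 4 lower. With an estimated correlation it called 0, and fry called 0 for a shift in one direction and 16 for change in either direction. Other splits of the same 6 arrays called up to 13 lists with the preset correlation.

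**Figure D4:**
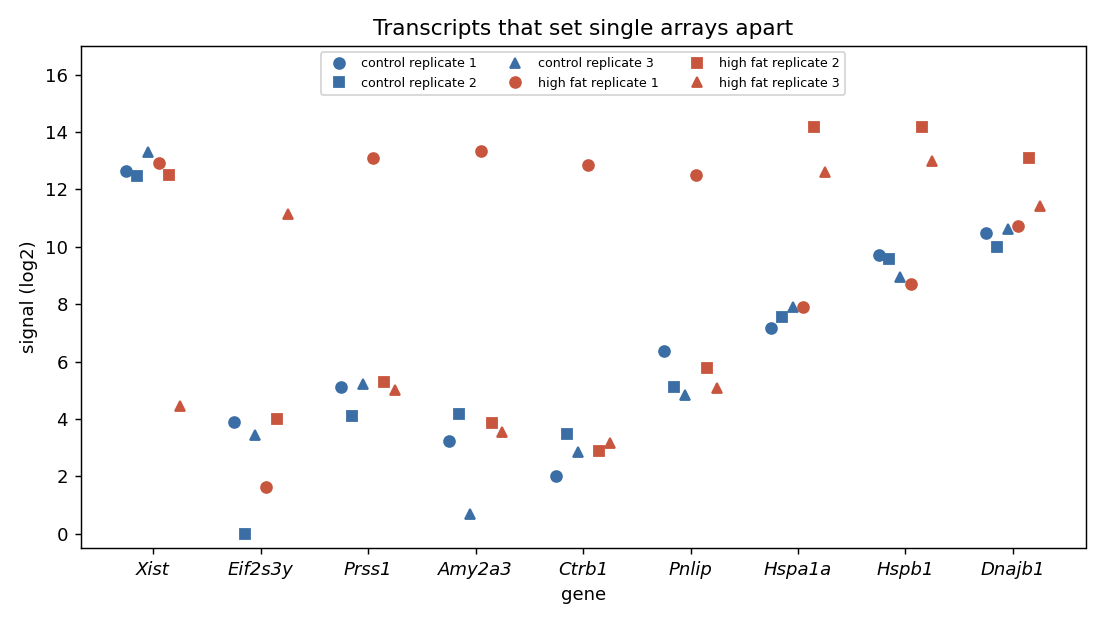
Log2 signal (vertical axis) of 9 transcripts (horizontal axis) that set single arrays apart, on each control (blue) and high fat (red) array. Xist is low and Eif2s3y high in high fat replicate 3, the pancreas genes Prss1, Amy2a3, Ctrb1 and Pnlip are high in high fat replicate 1, and Hspa1a, Hspb1 and Dnajb1 are highest in high fat replicates 2 and 3.

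Over all tested genes, arrays of the same group had a mean correlation of 0.970 and arrays of different groups 0.960 (Pearson, across genes, which are not independent replicates). The difference of 0.0101 was the largest of the 10 splits (exact permutation test, 1-sided p = 0.1, the smallest possible). The first principal component, with 35.2% of the variance, separated the groups. The 3' minus 5' difference of beta actin, a sign of RNA integrity, was 3.87 ± 0.56 (SD, n = 3) in controls and 3.45 ± 0.32 (SD, n = 3) in high fat pups (exact permutation p = 0.4). That of Gapdh was 1.25 ± 0.35 and 0.99 ± 0.30 (exact permutation p = 0.5), and the spike-in level was 12.08 ± 0.13 and 12.02 ± 0.16 (exact permutation p = 0.6). Control replicate 3 stood apart on both 3' minus 5' differences. Its beta actin value was 4.5 against 3.2 to 3.8 in the other arrays, and its Gapdh value 1.63 against 0.65 to 1.21. The 3' control probe sets of Gapdh and beta actin differed by -0.57 and -0.68, high fat minus control, and that of 5S rRNA by -1.14, each at an exact permutation p = 0.1.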

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

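The tests of the pancreas transcripts given here were chosen after the result was seen. High fat replicate 1 carried transcripts of the exocrine pancreas, in genes that were too dim on average to enter the tests. Against the highest control array, Ctrb1 was 9.36 log2 units higher in it, Amy2a3 9.18, Pnliprp1 8.22, Cel 7.63, Prss2 6.70, Cpa1 6.29 and Reg1a 4.05. Of the 14 pancreas genes on the array, 13 (92.9%) were more than 4 log2 units above every other array, as pancreas tissue or RNA in that sample would give. The exception was Cela1, at 10.42 to 11.85 in all arrays, which the liver samples share. In that array Amy2a3 was at 13.35, Prss1 at 13.08 and Ctrb1 at 12.84. A maternal effect on these genes is argued against, because in high fat replicates 2 and 3 the list's median was -0.050 relative to the control mean. When the tissue or RNA entered, at dissection or later, stays open.

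The Y-linked Eif2s3y was 7.24 log2 units higher in high fat replicate 3 than in the highest control array, and Xist was at 4.45 there. The other 5 arrays had Xist at 12.46 or above. Sex is not given in the labels, and only the high fat group holds both kinds of array. A sex covariate was planned only for the case that both groups did, and was not run. Without high fat replicate 3, 7 of the 8 lists kept their call.

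Probe sets with several genes or none named stayed outside the gene comparison, and 356 of the 4704 bright enough to test had an unadjusted p under 0.05 and at least 1.5-fold, 192 higher and 164 lower. That is 7.57%, against 6.67% of probe sets with 1 gene, and 2 of the 4704 passed the adjusted test over every probe set.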

How the results depend on the processing

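The alternatives with high fat replicates 1 and 3 left out and with RNA integrity as a covariate were chosen after seeing the data. The count of 4 genes was 7 at an adjusted p under 0.1 and 499 under 0.25, 1 without the brightness filter (Sox21), 8 with an intensity trend and 0 with the actin 3' minus 5' covariate, where limma gave 1120 genes at an unadjusted p under 0.05. It ranged from 0 to 3 with 1 array left out. Scd kept its call in 10 of 16 alternatives (adjusted p 0.00076 to 0.0841), Psat1 and Faxdc2 in 7 each and Retsat in 6, and the direction of each held in all 16. With high fat replicates 1 and 3 left out, 4 genes passed, none shared with the first 4, and the lone high fat array was assumed to vary like the controls. The 694 genes of the looser list were 1456 at 1.2-fold, 212 at 2-fold and 1285 over every probe set, and 662 to 846 with 1 array left out. The replicate numbers did not pair the samples, with correlations of same-numbered deviations from -0.136 to -0.127 and each number's arrays correlated better with those of another number. With the replicate block 0 genes passed in limma, with 1102 at an unadjusted p under 0.05, and 10 lists were called, the first 8 included.

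With an estimated correlation 0 lists were called, with adjusted p 0.496 for 6 of the 8, 0.685 for fatty acid oxidation and 0.771 for cell cycle. Fry called 0, at 0.142 for 5 of them, 0.348 for fatty acid oxidation, 0.831 for cell cycle and 0.189 for circadian clock. With 1 array left out, adjusted p ranged from 5.11e-06 to 0.817 for cell cycle, 0.00748 to 0.285 for circadian clock and 2.47e-05 to 0.0548 for fatty acid oxidation, and 6 to 8 of the 8 calls held. The clock was at 0.0999 with the mean of a gene's probe sets. Cell cycle was at 0.305 with the actin covariate and turned downward, at 0.326, with high fat replicates 1 and 3 left out. The other 5 lists kept call and direction in every alternative run but the estimated correlation and fry. Of 21 lists outside the threshold, 10 passed in some alternative, fatty acid synthesis in 6 of 18. Of 128 named genes, 34 moved by over 1.5 times with 1 array left out, none of them past the adjusted threshold. Dbp turned to -0.16 with the actin covariate and ranged from -0.36 to 0.69 with 1 array left out, Cyp7a1 from -0.0091 to 0.39 and Gzma from -0.23 to 0.072, with Gzma at 0.079 with high fat replicates 1 and 3 left out. Except where fewer arrays were used, the cause was not tested. The pseudocount was not run, since the values were already on a log scale, nor was sex as a covariate, which was planned only if both groups held both sexes. Without detection calls, what signal over background limits is unknown.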

Other observations

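The tests of the gene counts, of fasting and of the endothelial markers, and the lists of serine, synthetase and lipogenic genes, were chosen after results were seen. Genes that make serine and import amino acids lay higher in pups of high fat dams. Of 13 measured genes, 12 were higher, with a median of 1.00, and 7 passed when adjusted over the list alone. Beside Psat1, these were Phgdh (3.14), Slc7a1 (2.85), Asns (2.74), Slc7a11 (1.79), Mthfd2 of mitochondrial one-carbon metabolism (1.31) and Slc3a2, a partner of amino acid transporters (1.00). Camera's adjusted p over the added lists was 3.96e-09 (adjusted p = 0.0226 with an estimated correlation), which is no independent evidence, since members were picked from these arrays. Psph, Shmt2, Slc7a5, Slc38a2 and Atf5 lay between -0.09 and 0.20.

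The genes that passed are known targets of the amino acid response, so a hypothesis is that this response also reached the synthetases that charge tRNA with amino acids, which were not used to form it (Gars1, already seen, was left out). Of 18 measured, 14 were higher, and the median was 0.27 (95% bootstrap interval 0.04 to 0.56), above the 0.25 set in advance, though the interval reaches below it. Iars1 (0.70), Sars1 (0.61), Cars1 (0.60), Nars1 (0.58) and Mars1 (0.58) passed when adjusted over the list alone. Camera's adjusted p was 9.81e-05 (adjusted p = 0.110 with an estimated correlation). Other targets of the response went both ways, Trib3 at 0.88, Atf3 at 1.13 (SE 0.79), Ddit3 at 0.20, Sesn2 at -0.07, Chac1 at -0.27 and Ddit4 at -0.42, none past the test, and the stress response list was not called (adjusted p = 0.252). The median of 0.27 met its limit, but with these genes the response and its cause stay open.

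A male pup as the source of the shifted gene lists is argued against for 7 of the 8, which kept call and direction without high fat replicate 3, but not for cell cycle, which lost its call. All 8 kept theirs without high fat replicate 1, which argues against its pancreas RNA. A longer fast in high fat pups could raise PPAR alpha targets and lower sterol synthesis. Of 11 insulin-induced lipogenic genes, 4 (Scd, Me1, Thrsp and Pklr) were higher by more than 2 SE. That count met the limit set against a fast. The limit was written after results were seen, Scd, Me1 and Thrsp among them, so meeting it decides nothing. The list as a whole had 7 higher, 4 lower and a median of 0.39, which is the value of Srebf1 (SE 0.38). Camera's adjusted p over the added lists was 0.00498 (adjusted p = 0.109 with an estimated correlation), though the list was chosen after results were seen. The count ignored genes going the other way. Fasn and Gpam were lower by more than 2 SE. Angptl8 (-1.17), Igfbp1 (1.13) and Irs2 (1.61) lay on the side a fast would give. Without control replicate 3, Fasn was at -1.0, Igfbp1 at 0.64 and Irs2 at 1.05. Fasting stays open. The real split of the arrays called 8 lists and the highest other 13. Of the 10 splits, 6, the real one included, called 8 or more, which met the limit set in advance for chance. The number of lists called thus does not set the real split apart, and 10 splits are too few to exclude chance. Maternal diet, litter and chance stay open. With the covariate for RNA integrity 7 of the 8 lists kept call and direction, and cell cycle lost its call (camera adjusted p = 0.305). Whether the high heat shock genes of high fat replicates 2 and 3 relate to the shifted lists was not tested.

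Fewer non-parenchymal cells of every kind would lower all their markers alike. The endothelial median was below that of 34 macrophage and stellate markers by a difference of -0.56 (95% bootstrap interval over markers, not pups, -0.81 to -0.34). Against stellate markers alone it was lower by 0.45 to 0.79 in every high fat array, which argues against a loss of every kind, but in high fat replicate 2 it was about that of macrophage markers (-0.40 and -0.38), so a shared loss of these cells there stays open. Dilution by pancreas RNA is also argued against, since the endothelial median was -0.55 without high fat replicate 1. A change within endothelial cells, or fewer of them, with maternal diet remains a hypothesis that transcript levels of whole liver could not separate.

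For the gene counts too, 10 splits are too few for a share under 0.05. The real split gave 4 genes past the adjusted threshold and the highest other 0, and 694 genes of the looser list against 352, with 1 split in each case, the real one, reaching as many.

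Heat shock genes stood apart in high fat replicates 2 and 3, where Hspa1a was at 14.19 and 12.60, Hspb1 at 14.17 and 13.00, Dnaja4 at 11.87 and 10.76 and Dnajb1 at 13.10 and 11.44. In the other 4 arrays, control and high fat, Hspa1a was at 7.18 to 7.91, Hspb1 at 8.70 to 9.73, Dnaja4 at 8.15 to 8.42 and Dnajb1 at 9.98 to 10.71.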
